A study of Mus musculus with 24 samples.

How the data were processed

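Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed for the trimethylated histone mark H3K4me3, a mark of active promoters, on leukemic splenocytes of Eµ-TCL1A mice. These mice carry a TCL1A transgene that is active in B cells and develop a disease resembling chronic lymphocytic leukemia. The labels describe 24 libraries in 4 groups of 6. Wild-type and KDM1A-knockdown cells each have 6 immunoprecipitated and 6 input libraries, made from 3 biological replicates with 2 technical replicates each.

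Per the submitters' processing notes, Bowtie2 2.2.9, SAMtools 1.6, MACS2 2.2.6 and the genome build GRCm39 were used. The order, the settings, any filter, and whether replicates were pooled before the comparison are not given in the sources used here. The authors deposited 3 region lists that compare both conditions as a whole. Per the file headers, they hold regions unique to the knockdown (KD regions), regions unique to the wild type (WT regions) and regions common to both. Each file gives chromosome, start, end, name and a score. The deposited score is 1 value per region. It lay above 3 in every KD and WT region and below 3 in every common region, and the file headers do not define it. The differential mode of MACS2 writes lists of this layout, with a mean log likelihood ratio as the score, but neither headers nor labels name that mode. The scores are the authors' own and were used only to rank and filter regions within this comparison. The score of a common region carries no direction.

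The lists give no value per library, no read count and no depth. The spread between biological replicates could therefore not be measured, no p-value is given, and the scale on which the conditions were compared is not known. Shares of regions are given with 95% Wilson intervals, which cover counting error only and treat regions as independent. The range over the 19 autosomes is given as a second, wider measure of spread. A sequencing depth cannot be attached to any value for the same reason.

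Regions were analysed with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9. Lists were read as deposited. The 2 WT regions and 26 common regions on unplaced contigs were left out of the comparisons. KD and WT regions together are called one-sided regions, and the KD share is the percentage of them that were KD regions. A region was near a common region if the gap between them was at most 1 kb. Regions of all 3 kinds within 1 kb of each other were joined into domains. Within a domain that held a common region, a one-sided region was called inner if common sequence lay on both sides of it and edge if it did not. Expected values came from 100 random placements of the KD and WT regions on their own chromosomes, between the first and the last region of each chromosome. Windows of 5 Mb were used if they held at least 20 one-sided regions. Since this minimum depends on the regions counted, chromosome 15 was also compared over all windows with a common region, by KD regions per 100 common regions. The code for gaps, domains and windows was tested on 2095 simulated one-sided regions and recovered 100% of the quantities that had been built into them. Coordinates are 1-based positions on GRCm39.

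The comparisons, the alternatives and the rule for named regions were fixed before the data were examined, except where a choice is said to have been made later. The rule named the 10 KD and 10 WT regions with the highest score and the windows with the 3 highest and 3 lowest KD shares. It also asked for regions at promoters and for members of preset gene lists. The gene table at hand is for the assembly GRCm38.p6, a different build, and coordinates were not converted between builds. Assignment of regions to genes, promoters and exons, the gene lists, the sequence composition of the regions, and the Kdm1a locus were therefore not analysed here, and the highest-scoring regions were taken irrespective of promoters. The immunoglobulin loci, planned to be counted apart, were not delimited for the same reason. The level of Kdm1a in the knockdown was not analysed here either, since the lists hold no expression data. Alternatives were a stricter score (at or above the median of the own list, or at least 5), a length of at least 500 bp, joining of one-sided regions within 1 kb, autosomes alone, covered length in place of counts, gaps of 0 and 5 kb, and windows of 2 Mb. A score of at least 10, leaving out chromosome 15, windows with any one-sided region, and domains of touching regions alone were added after seeing the data. The domains with their edge and inner positions, the classes of windows by common length, the comparison over windows with a common region, the further score minimums and the sites described one by one were likewise chosen after the data were examined.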

Results

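H3K4me3 was mapped in leukemic splenocytes of Eµ-TCL1A mice, a model of chronic lymphocytic leukemia, with KDM1A intact or knocked down. KDM1A (LSD1) is a histone demethylase that removes methyl groups from mono- and dimethylated H3K4. Each condition had 3 biological replicates with 2 technical replicates, as 6 immunoprecipitated and 6 input libraries. The deposited result is 1 comparison of the conditions as a whole. It comprised 14823 regions unique to the knockdown (KD regions), 5326 unique to the wild type (WT regions) and 43276 common to both. The lists give neither read depth nor values per replicate. None of the differences below could therefore be set against the spread between biological replicates, and no test across replicates was possible.

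The first question was in which direction H3K4me3 differed between the conditions. Regions listed as unique to the knockdown outnumbered those listed as unique to the wild type 2.78 to 1. On the assembled chromosomes 14823 of 20147 one-sided regions were KD regions, a share of 73.6% (95% Wilson interval 73.0 to 74.2%). KD regions covered 7.75 Mb and WT regions 3.31 Mb, against 69.6 Mb of common regions. KD regions outnumbered WT regions on 19 of 19 autosomes, where the KD share had a median of 71.6% and ranged from 58.0% on chromosome 12 to 94.4% on chromosome 15. Without chromosome 15 the KD share was 71.6% (70.9 to 72.2%).

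KD regions were shorter and scored lower than WT regions. The median length was 341 bp (quartiles 267 and 548 bp) for KD regions, 429 bp (303 and 698 bp) for WT regions and 870 bp for common regions. The median score was 4.49 (3.86 and 5.63) for KD regions and 5.29 (4.10 and 8.22) for WT regions. The KD share was 64.9% (63.8 to 65.9%) among regions scoring at least 5 and 50.6% (48.8 to 52.4%) at a minimum of 8. At a minimum of 10, which was chosen after seeing the data, 841 KD and 904 WT regions remained, a KD share of 48.2% (45.9 to 50.5%), and KD regions outnumbered WT regions on 8 of 19 autosomes. At a minimum of 20 it was 60.4% (54.6 to 65.9%), from 171 KD and 112 WT regions.

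**Figure D1:**
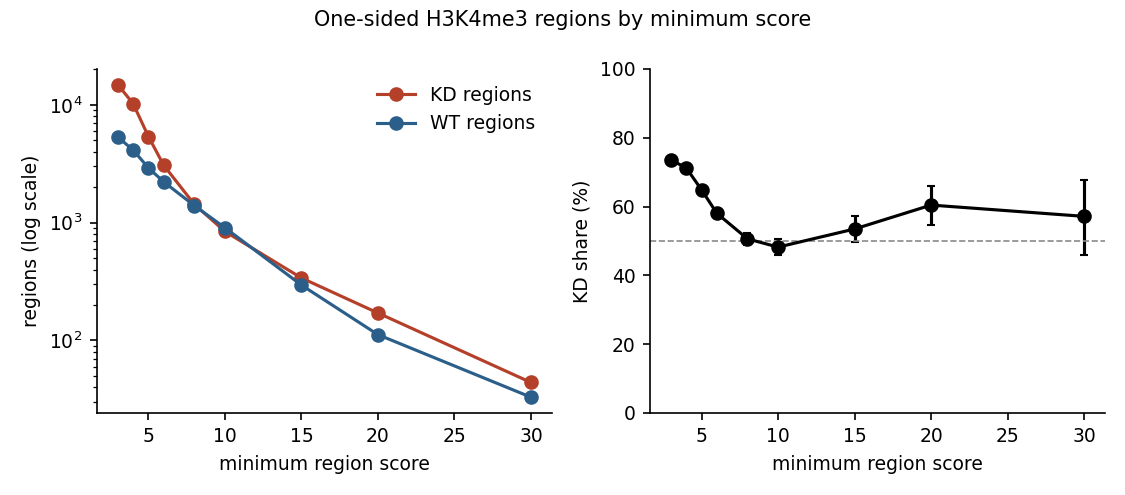
Left, the number of KD and WT regions (log axis) with at least the score on the x axis. Right, the KD share of these regions in percent, with 95% Wilson intervals and a dashed line at 50%; the share was 73.6% for all regions and 48.2% at a minimum score of 10.

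The second question was whether the differences arose at sites marked in both conditions or at separate sites. Most lay beside shared H3K4me3. Of the KD regions 74.2% (73.5 to 74.9%) lay within 1 kb of a common region, as did 73.5% (72.3 to 74.7%) of the WT regions, against 5.99% and 5.65% of randomly placed regions. If an enriched stretch was cut by score into common and one-sided pieces, contact would follow from the cutting itself. The random placement does not allow for this, so it does not show that differences gather at shared sites. The types of contact differed. Direct contact with a common region was seen for 54.6% (53.8 to 55.4%) of KD regions and 67.0% (65.7 to 68.2%) of WT regions. Regions within 1 kb but without contact made up 19.6% (19.01 to 20.3%) of KD regions and 6.52% (5.89 to 7.21%) of WT regions. At the far end, 2110 KD regions (14.2%) and 1171 WT regions (22.0%) lay over 5 kb from any common region. These distant regions had the highest median scores of their lists, 6.35 for KD and 7.09 for WT regions. The strongest regions of the lists differed in place. Among regions scoring at least 10, 24.1% (21.4 to 27.1%) of KD regions and 60.1% (56.8 to 63.2%) of WT regions lay within 1 kb of a common region.

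Joining all regions within 1 kb gave 28503 H3K4me3 domains. Of these, 15645 (54.9%) held common regions alone, with a median length of 1738 bp. A further 5708 domains held common and KD regions, and 2558 (8.97%) held common and WT regions. KD regions alone formed 2848 domains of a median 384 bp (9.99%), and WT regions alone formed 1190 domains of a median 624 bp (4.18%). The remaining 554 domains held both KD and WT regions, with a median length of 7072 bp.

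Within shared domains, KD regions lay at the outer edge more often than WT regions did. The edge share was 46.6% (45.7 to 47.5%) of 11464 KD regions and 26.4% (25.1 to 27.8%) of 3980 WT regions, the others being flanked by common sequence on both sides. The separation was present in each score class. Among regions scoring 3 to 4 it was 37.5% (36.1 to 39.0%) against 25.7% (23.1 to 28.4%). Among those scoring 8 or more it was 65.2% (60.9 to 69.3%) of KD regions against 13.5% (11.4 to 15.96%) of WT regions. On chromosome 15 the KD edge share was 39.9% (37.3 to 42.5%), and on the other autosomes it was 47.5% (46.5 to 48.5%). If enriched stretches were cut by score, edge and inner positions also depend on the cutting and on the unknown scale of the comparison. Whether a difference in scale or enrichment between the conditions produced the edge pattern was not tested.

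**Figure D2:**
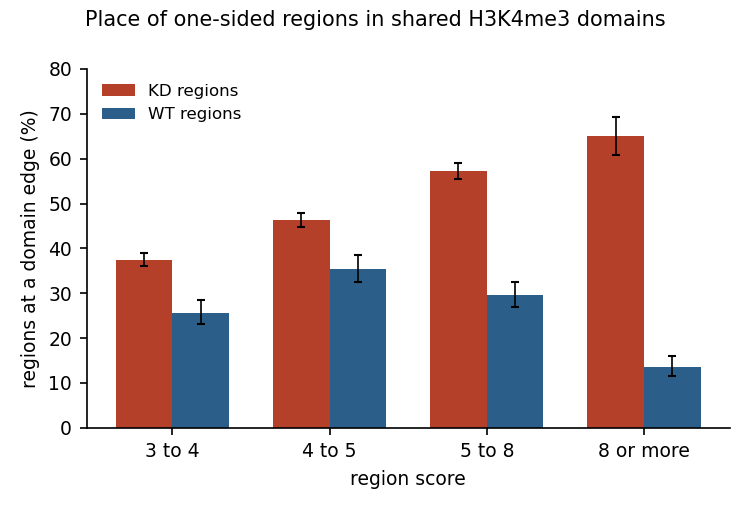
The percentage of KD and WT regions in shared domains that lay at the domain edge (y axis), by class of region score (x axis), with 95% Wilson intervals. Among regions scoring 8 or more it was 65.2% of KD and 13.5% of WT regions.

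The third question was how the differences were spread over the genome. Chromosome 15 stood apart from every other autosome. It held 1646 KD and 98 WT regions, a KD share of 94.4% (93.2 to 95.4%), while the other 18 autosomes ranged from 58.0 to 83.2%. It carried 11.1% of all KD regions, 1.84% of all WT regions and 4.84% of common regions. KD regions there numbered 78.6 per 100 common regions, against a median of 32.2 (range 23.7 to 40.8) on the other autosomes, and WT regions 4.68 per 100, against 12.8 (8.22 to 17.2). The score of its common regions, which carries no direction, had a median of 1.06, against medians of 0.453 to 0.581 on the other autosomes. Chromosome 15 carries the proto-oncogene Myc among many other genes. No region was assigned to any of them.

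The sex chromosomes differed from the autosomes and from each other. On X, 70 KD and 210 WT regions gave a KD share of 25% (20.3 to 30.4%), and WT regions numbered 27.4 per 100 common regions. On Y there were 19 KD regions, 1 WT region and 12 common regions. Of these, 8 KD regions, the WT region and 4 common regions lay in the proximal part, between positions 897231 and 3997252. The other 11 KD regions and the other 8 common regions lay at the distal end, between 90729130 and 90822104.

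**Figure D3:**
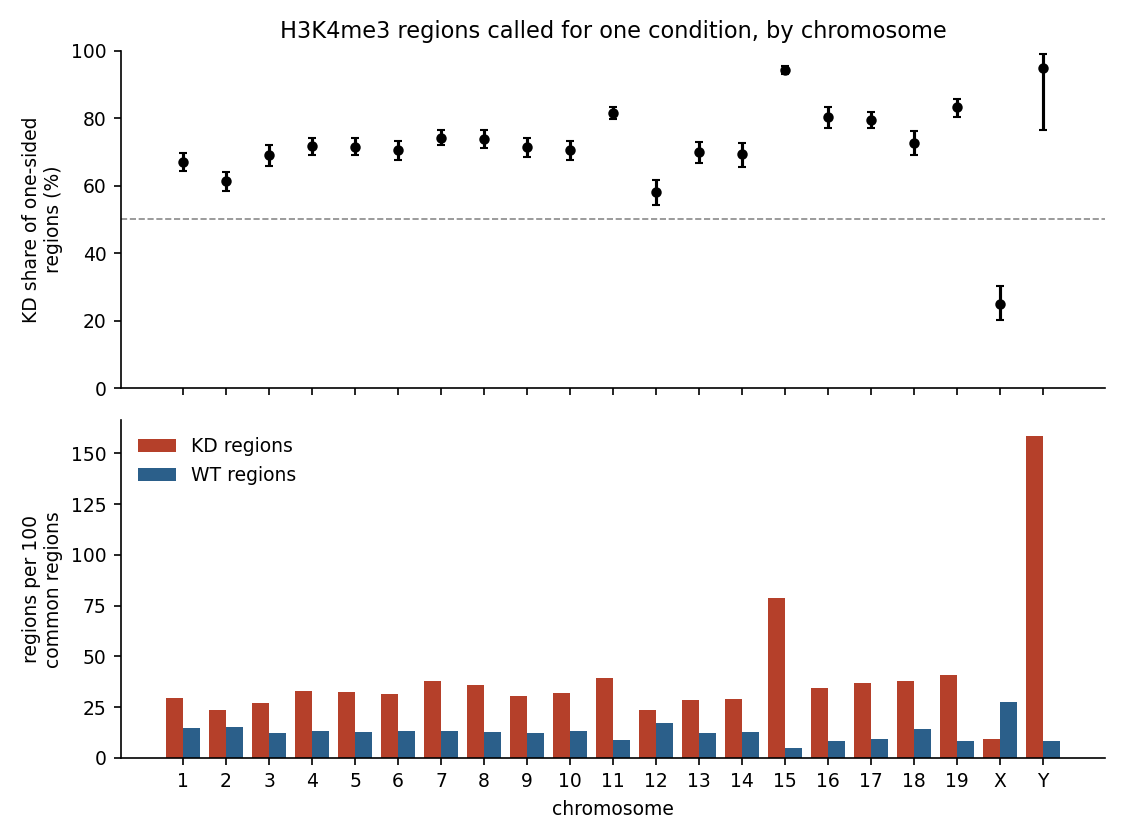
Top, the KD share of one-sided regions on each chromosome in percent, with 95% Wilson intervals and a dashed line at 50%. Bottom, KD and WT regions per 100 common regions; chromosome 15 is the highest autosome for KD regions (78.6 per 100) and the lowest for WT regions (4.68 per 100), and on X the order is inverted.

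Along the chromosomes, 335 windows of 5 Mb held at least 20 one-sided regions, and KD regions were the majority in 294 of them (87.8%). The 16 such windows of chromosome 15 lay between 78.6 and 98.2%, and the median of 314 windows on the other autosomes was 74.4% (quartiles 63.8 and 81.3%). This minimum favours windows rich in one-sided regions. Over all windows with a common region, whatever their one-sided regions, the 18 windows of chromosome 15 held 39.7 to 100 KD regions per 100 common regions (median 77.4), against a median of 29.4 (quartiles 20 and 37.9) in 465 windows of the other autosomes. WT regions were the majority in 36 windows, 4 of them on X. The lowest KD shares were 1 of 42 regions on chromosome 1 at 185 to 190 Mb, 1 of 21 on X at 10 to 15 Mb and 3 of 36 on X at 100 to 105 Mb. The highest were 22 of 22 on chromosome 6 at 105 to 110 Mb, 20 of 20 on chromosome 5 at 60 to 65 Mb and 112 KD and 2 WT regions on chromosome 15 at 55 to 60 Mb. Among the 314 windows of autosomes other than 15 with at least 20 one-sided regions, KD shares were higher where H3K4me3 was denser. These windows were ranked by common length into 4 classes, and windows below that minimum were not included. In the class with the least (36.3 to 111 kb) the pooled KD share was 65.1%, and in the class with the most (241 to 625 kb) it was 77.9%.

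**Figure D4:**
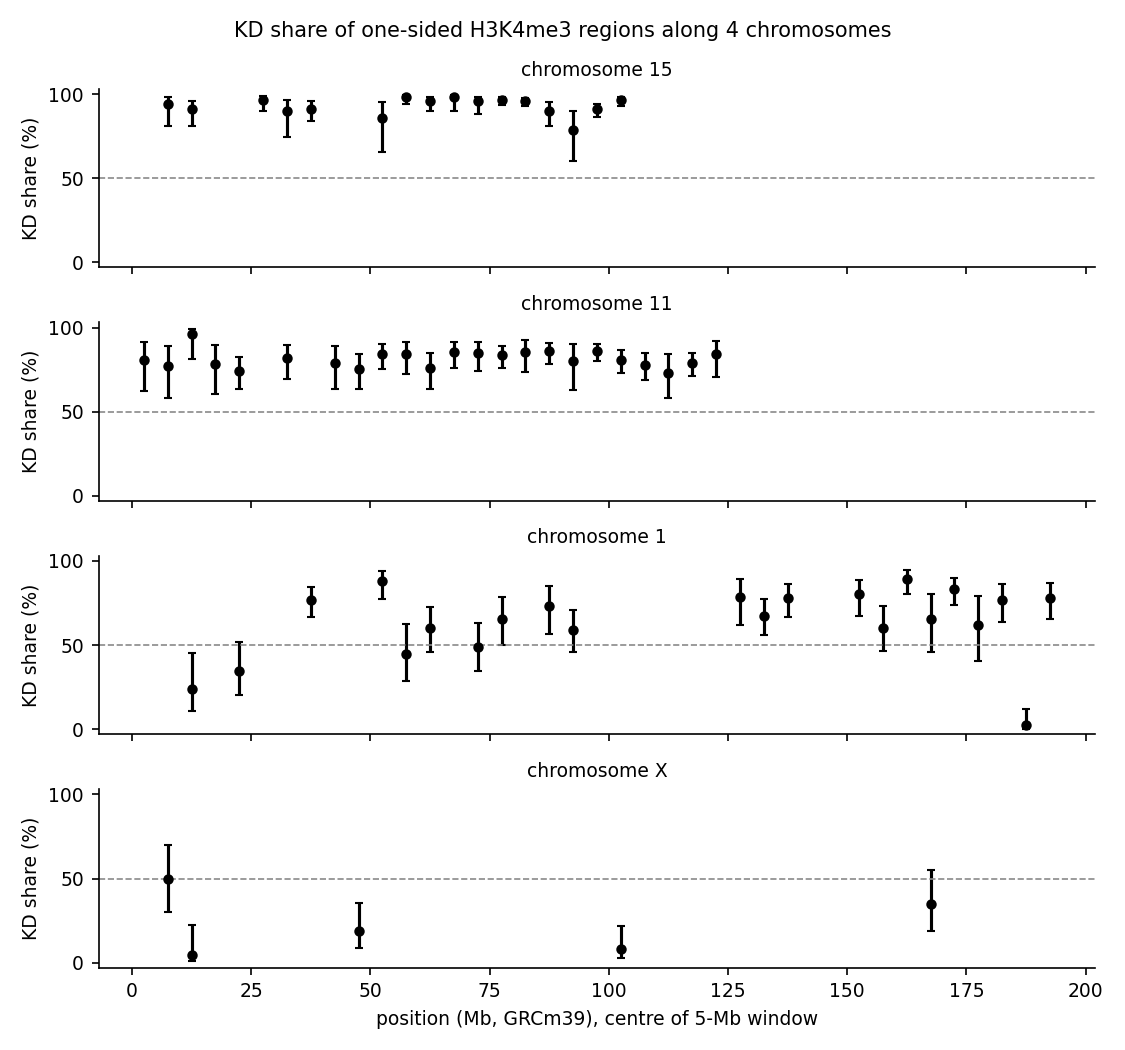
KD share of one-sided regions in percent in 5-Mb windows with at least 20 such regions along chromosomes 15, 11, 1 and X (GRCm39), with 95% Wilson intervals and a dashed line at 50%. Windows of chromosome 15 lie between 78.6 and 98.2%, and the lowest window of chromosome 1, at 185 to 190 Mb, holds 1 KD region among 42.

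The WT regions with the highest scores were concentrated on X, most of these within a short string of neighbouring regions. The labels give no sex, so these X regions cannot be ascribed to the knockdown rather than to sex. The highest, with a score of 104.7, spanned positions 102523433 to 102527791. Of the 10 highest WT regions, 5 others lay on X between 49638770 and 49686808, with scores of 56.0 to 73.0. They belonged to a string, singled out after its values were seen, of 20 WT regions between 49638770 and 49712595 that covered 14730 bp, had a median score of 44.3 and included no common region. A single KD region, at 49625598 to 49626797 with a score of 25.3, lay beside it. The remaining 4 lay on chromosome 12 at 92855961 to 92858094 (score 65.2), chromosome 1 at 181749101 to 181750613 (60.4), chromosome 10 at 83243041 to 83243590 (53.6) and chromosome 9 at 56513230 to 56514265 (52.6).

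The 10 KD regions with the highest scores were spread over 8 chromosomes. The highest, on X at 105247216 to 105247847, had a score of 87.2. Of the 10, 3 lay near the distal end of chromosome 12, the end that bears the immunoglobulin heavy-chain locus. They were at 113536580 to 113538293 (score 85.9), 113393389 to 113395503 (54.9) and 113061828 to 113062187 (51.2). This stretch, from 113036891 to 113860593, held 9 KD, 12 WT and 27 common regions. Its limits were not matched to the locus, and clonal rearrangement there was not tested. A KD region of 8184 bp on chromosome 14 at 118008944 to 118017127 (score 48.5) was the second longest KD region and lay 145469 bp from the nearest common region. The others lay on chromosome 2 at 179617326 to 179618235 (72.4), chromosome 7 at 126365179 to 126368756 (59.9), chromosome 6 at 48024963 to 48025452 (54.0), chromosome 1 at 136635439 to 136635946 (51.2) and chromosome 18 at 82710679 to 82711120 (47.4).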

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

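The KD share stayed above 50% under every alternative run except a score minimum of 10, and the edge share stayed higher for KD than for WT regions under every alternative run. A score of at least 10, leaving out chromosome 15, windows with any one-sided region and domains of touching regions alone were chosen after seeing the data. Of 70 alternative values, 30 stayed within the counting interval of the reported value or, for a count, within 1.5 times of it, and the cause of the other shifts was not tested. With a score of at least 5, the KD share was 64.9% in all and 90.3% on chromosome 15, 55.2% of KD and 66.8% of WT regions were near a common region, and 59.1% and 22.8% lay at an edge. With a score of at least 10, the KD share was 48.2% in all and 84.7% on chromosome 15, KD regions were the majority on 8 autosomes and in 0% of windows (of 1 window left), 24.1% of KD and 60.1% of WT regions were near a common region, and 52.8% and 11.2% lay at an edge. With scores at or above the median of the own list, which fixes the overall share, chromosome 15 stood at 93.1%, windows with a KD majority at 93.2%, nearness at 61.7% and 66.1%, and edges at 54.8% and 22.3%. Regions of at least 500 bp gave a KD share of 66.6% in all and 16.2% on X, nearness of 71.9% and 65.7%, and edges of 51.6% and 32.5%. Joining regions within 1 kb gave a share of 70.9% in all, 91.8% on chromosome 15 and a KD edge share of 54.1%. The share was 74.2% on autosomes alone and 70.1% by covered length. Without chromosome 15 it was 71.6%, with 73.3% of KD regions near a common region and 47.5% at an edge. Nearness was 54.6% (KD) and 67.0% (WT) for contact alone, and 85.8% and 78.0% within 5 kb, so its order depends on the gap. Over all windows with any one-sided region, 74.4% had a KD majority. With domains of touching regions alone the KD edge share was 44.4%. No paired analysis was possible because the lists hold no values per replicate, and for the same reason no replicate could be left out. Alternatives about promoter windows, gene sets, random gene lists and overlap with promoters were not run, since no annotation of the build was used. Depth is not known, so what it limits cannot be stated.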

Other observations

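Several sites outside the preset summaries had strings of regions in 1 direction, found after the data were seen. On chromosome 1, 31 WT regions and no KD region lay between positions 189435639 and 189655486, covering 36398 bp with a top score of 48.9 and a median of 5.64. Without the 5-Mb window that holds them, the KD share of chromosome 1 was 69.4% (95% Wilson interval 66.6 to 72.0%). On X, 18 WT regions and no KD region lay between 102516966 and 102667083, interspersed with 16 common regions, and they included the WT region with the highest score of all. The longest KD region, of 9249 bp on chromosome 7 at 126737043 to 126746291, touched common regions and scored 9.59. The longest WT region, of 8866 bp on chromosome 1 at 14372046 to 14380911, lay 157206 bp from the nearest common region and scored 15.4.

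Of the tests that follow, the one that leaves out the densest windows of chromosome 15 was set before its result was seen, and the others were chosen after the result they concern had been seen.

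The excess of KD regions is not the work of chromosome 15, since the KD share without it was 71.6%, with an interval (70.9 to 72.2%) well above 50%. In number it was carried by regions of low score, with 1428 KD and 1394 WT regions left at a minimum of 8. On the autosomes other than 15, KD regions made up 46.9% (44.5 to 49.4%) of regions scoring at least 10. That share was not computed at other minimums. Over all chromosomes, 10 was the only minimum tried with a KD share below 50%. The share over all chromosomes was 53.5% (49.6 to 57.3%) at a minimum of 15 and 60.4% at 20. A difference in scale, depth or enrichment between the conditions is a candidate explanation for the bulk of the excess, and so is a small and widespread effect of the knockdown. The number of columns with values per library is 0, which keeps the knockdown itself open, and the knockdown and a technical difference cannot be told apart here.

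The excess on chromosome 15 is consistent with a gain of the whole chromosome in the knockdown cells of at least some animals, a hypothesis, and equally with its loss in wild-type cells, which was not tested apart. All 18 of its windows with a common region held more KD regions per 100 common regions than the median window of the other autosomes. A few strongly changed loci are argued against by the KD share without its 4 densest windows, 93.5% (91.6 to 95.1%), which lies above the highest other autosome (83.2%). Its density of H3K4me3 is argued against too, since 18 of these 18 windows exceeded the upper quartile, in KD regions per 100 common regions, of other autosomal windows of similar common length. Open are how many animals contribute and whether the input libraries show the same excess, which was not analysed here, and a response of this chromosome to the knockdown was not tested.

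The WT excess on X and the KD excess on Y may come from a different share of male and female animals in the conditions, a hypothesis, as the labels give no sex. Outside the distal end of Y, 8 of 9 one-sided regions were KD regions, and 4 common regions there show that Y-linked signal was called in both conditions. The 2 focal clusters do not make up the whole WT excess on X. Without the windows at 45 to 50 and 100 to 105 Mb the KD share of X was 28.8% (23.1 to 35.2%), below the lowest autosome (58.0%). Whether the clusters and the remaining excess share a cause was not tested, so this value does not decide on sex. Loss of a sex chromosome in the leukemic cells of some animals was not tested and stays open.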
